A study of Mus musculus with 36 samples.

How the data were processed

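The deposited table holds counts of single-end RNA-seq reads per gene, which per the file headers the authors made with featureCounts 1.5.2 in reverse-stranded mode (setting 2), from primary alignments with a mapping quality of at least 1, on Ensembl release 87 gene models. The submitters' processing notes name GSNAP 2017-03-17 as the aligner and GRCm38 (mm10) as the genome build. Read trimming and duplicate handling are not given in the sources used here. Per the sample notes, Trizol RNA went through poly(A) selection, random-primed cDNA synthesis, a strand-specific ScriptSeq kit and rRNA removal.

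The 36 libraries are mouse stem cells of 3 conditional lines (Bod1L, Setd1a and Mll2, the last targeting the gene Kmt2b). Sample titles name embryonic stem cells (ESC) in 2i and FCS and EpiSC in the third medium, so cell type and medium changed together there. Each line has knockout and wild-type cells in 3 media, with 2 replicates labelled biological. The 2i medium held LIF, PD0325901 and CT99021, FCS held LIF and serum, and EpiSC medium held Activin A and FGF2. Labels name tamoxifen for knockout cells, so treatment and genotype were confounded. The replicates are cultures of 1 line each, and p values measure the spread between these. Library numbers fell in an earlier run (23 libraries) and a later run (13 libraries: all 12 in EpiSC medium and Setd1a knockout 2i replicate 1).

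The table had 49763 lines for genes and spike-ins, of which 92 ERCC spike-ins held 0 counts and were removed, leaving 49671 genes. Symbols came from GENCODE M21 by Ensembl identifier, with 345 genes left without one. Gene counts per library ran from 24.5 to 40.6 M (median 32.6 M), and mitochondrial genes took 1.98% to 7.71%. The targeted genes on GRCm38 were Bod1l (ENSMUSG00000061755, chromosome 5, 41787538 to 41844315), Setd1a (ENSMUSG00000042308, chromosome 7, 127776670 to 127800122) and Kmt2b (ENSMUSG00000006307, chromosome 7, 30568858 to 30588726).

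Groups, comparisons, the 26 lists, most settings and the rule for naming genes were fixed before the data were examined. Settings that leave out a library picked for its values, the block in list and similarity tests, the line differences of the lists and the mitochondrial translation list were chosen afterwards. Counts were fitted with edgeR 4.0.16 (TMM size factors, filterByExpr with a minimum count of 10, quasi-likelihood F tests) in 1 model of 18 groups with 18 residual degrees of freedom, on 23501 genes. Averages weighed the 3 media equally. Tests of a knockout effect that differs between media, and of differences among the 3 wild-type lines, were F tests of 2 contrasts. All other tests had 1 contrast. Every adjusted p of a gene is an edgeR Benjamini-Hochberg value called below 0.05 unless another tool is named. SE values are those of the edgeR log2 fold changes, and SD values are between libraries. Other fits used DESeq2 1.42.0 with R 4.3.3, limma 3.58.1 and the data.table package (1.17.8). Replicate numbers were checked for pairing by the correlation of replicate differences in knockout and wild-type cells, which was 0.673, 0.547 and 0.737 for Bod1L in 2i, FCS and EpiSC medium, 0.166, 0.236 and 0.707 for Setd1a, and 0.408, 0.532 and 0.537 for Mll2. The labels give replicate numbers and state no pairing, so pairing was inferred from these same data. On that basis a second fit with the 18 pairs as a block and 9 knockout effects (9 residual degrees of freedom) was run.

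The 26 gene lists (563 members, 554 tested) came from general knowledge and were written down before the data were examined. They cover COMPASS subunits, homologous recombination, the Fanconi anaemia pathway, damage checkpoint signalling, excision and mismatch repair, end joining, p53 targets, replication and S phase, G2 and mitosis, general, naive and formative pluripotency, mesendoderm, primitive endoderm, neural, trophoblast, feeder, 2-cell-like, germline and Hox genes, ERK, Wnt and integrated stress responses, cholesterol synthesis, mitochondrially encoded genes and replication-dependent histones. Lists were tested with camera at a preset correlation of 0.01 over 312 list and comparison pairs, and the 140 repair genes over 12 comparisons. Of these, homologous recombination, the repair list in all Setd1a comparisons, and the repair list for Bod1L in 2i, in EpiSC medium and on average held with an estimated correlation, except homologous recombination for Bod1L in FCS and EpiSC medium. None of these calls held with the block and an estimated correlation together. Head-to-head neighbours started within 1000 bp on the opposite strand. The 10000 random lists were matched in 20 expression bins of all tested genes, and drawn from protein-coding genes for the head-to-head test. The test of GC content and gene length used genes of at least 5 CPM.

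Some genes that pass the rule below are not reported here. Named genes are otherwise, in rank order and without skipping, the targeted genes, the genes of highest and lowest log2 fold change per comparison, up to 4 members per list by adjusted p and the top genes per difference test. Each passed adjusted p below 0.05, a mean of at least 5 CPM in the higher group and no overlap between groups in single comparisons (for averages, the same side in all 3 media). Symbols of predicted genes, Riken clones, pseudogenes and small RNAs were passed over. The head-to-head pairs named as examples, Bod1l in its own line and genes of the mitochondrial translation list stand outside the rule. In a simulation 50 genes were changed per fold in Bod1L 2i libraries, with a set variation between libraries and an effect shared by each pair. The fit without the block recovered 0, 2, 25 and 46 at folds of 1.5, 2, 3 and 4, with 0 false calls. The blocked fit recovered 7, 23, 48 and 49, with 5 false calls. The shared effect was built in, so these numbers do not measure the gain from the block in the real data.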

Results

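Bod1l, which codes for a chromatin factor that protects stalled replication forks, fell in Bod1L knockout cells in each of the 3 media. In 2i its level was 61.2 ± 1.38 CPM (counts scaled to library size; mean ± SD, n = 2) against 206 ± 9.57 in wild-type cells, a log2 fold change of -1.75 ± 0.243 (± SE; adjusted p = 7.84e-04). In FCS it was 39.8 ± 8.68 against 299 ± 63.9 CPM (-2.91 ± 0.253; adjusted p = 1.53e-06), and in EpiSC medium 44.0 ± 8.78 against 170 ± 5.71 CPM (-1.95 ± 0.244; adjusted p = 1.95e-04). Averaged over the media, knockout cells held 21.7% of the wild-type level (48.3 ± 11.6 against 225 ± 66.4 CPM, n = 6; -2.21 ± 0.142; adjusted p = 1.83e-09). The 6 knockout libraries ranged from 33.6 to 62.2 CPM, and the next lowest of the 36 libraries held 166 CPM. Without the Bod1L knockout 2i replicate 2 library, Bod1l in 2i had an adjusted p of 0.0512. In the Setd1a and Mll2 lines the averaged log2 fold changes of Bod1l were 0.20 ± 0.136 (adjusted p = 0.396) and -0.14 ± 0.136 (adjusted p = 0.893).

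Setd1a and Kmt2b, which code for histone H3 lysine 4 methyltransferases, were detected in every knockout library of their own lines. Setd1a in the Setd1a line was 42.3 ± 2.16 against 53.8 ± 2.13 CPM in 2i (-0.35 ± 0.241; adjusted p = 0.583), 37.7 ± 0.565 against 56.8 ± 2.93 in FCS (-0.59 ± 0.241; adjusted p = 0.576) and 38.8 ± 1.51 against 44.5 ± 5.07 in EpiSC medium (-0.20 ± 0.241; adjusted p = 0.791). The average was 39.6 ± 2.47 against 51.7 ± 6.37 CPM, 76.9% of wild type (-0.38 ± 0.139; adjusted p = 0.0957). With the inferred pairs as a block Setd1a fell by 0.38 (adjusted p = 0.0285). The replicate differences behind that pairing correlated by only 0.166 in 2i and 0.236 in FCS in this line. Kmt2b in the Mll2 line was 129 ± 12.8 against 157 ± 40.9 CPM on average, 82.5% of wild type (-0.28 ± 0.167; adjusted p = 0.744). Its log2 fold changes were 0.05 in 2i (adjusted p = 0.988), -0.51 in FCS and -0.36 in EpiSC medium. The library labelled Mll2 wild type in 2i, replicate 2, held 89.6 CPM of Kmt2b, below the Mll2 knockout libraries in 2i (145 and 136 CPM) and its partner (183 CPM). Without that library the 2i log2 fold change of Kmt2b was -0.38, and without its partner, replicate 1, it was 0.65. In the Bod1L line Setd1a and Kmt2b had averaged log2 fold changes of -0.08 and 0.10, Setd1a in the Mll2 line 0.12 and Kmt2b in the Setd1a line 0.18 (adjusted p = 1, 1, 0.929 and 0.553). The gene totals include exons outside a deletion, so these levels check the loss of Setd1a and Kmt2b only weakly.

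**Figure D1:**
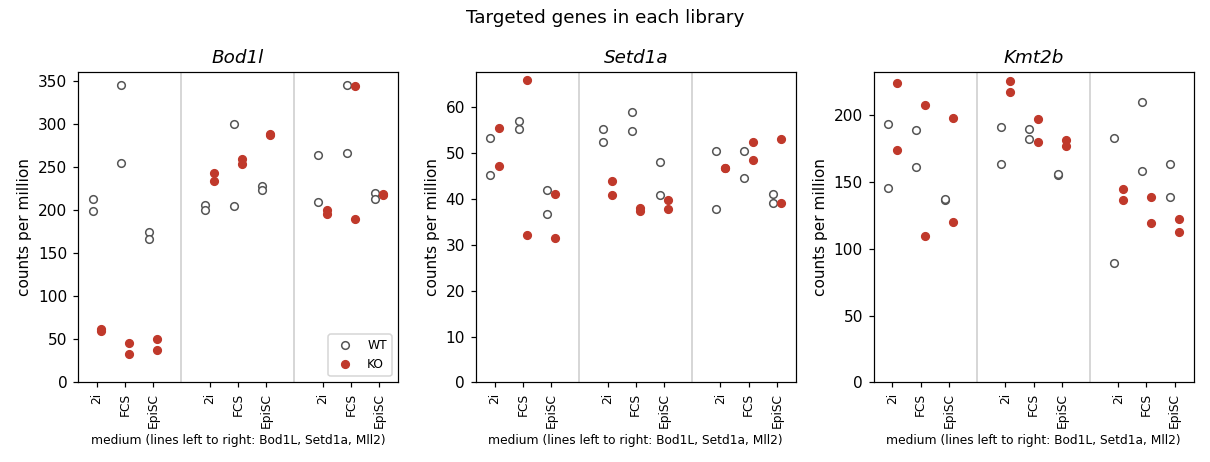
Bod1l, Setd1a and Kmt2b in each of the 36 libraries, in CPM, by line, medium and genotype. Points are single libraries, 2 per group.

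Bod1L knockout cells lost transcripts of a small group of genes. Averaged over the media, the lowest was Ccdc191 (2.00 against 19.5 CPM, n = 6; -3.34 ± 0.25; adjusted p = 1.25e-08). Next came Cbr4, coding for a mitochondrial carbonyl reductase (1.91 against 17.3 CPM; -3.21 ± 0.301; adjusted p = 5.29e-07), and Gatb, for a mitochondrial glutamyl-tRNA amidotransferase subunit (2.89 against 17.4 CPM; -2.59 ± 0.183; adjusted p = 4.73e-09). Alg8, for an N-glycosylation glucosyltransferase, fell by 2.54 ± 0.302 (adjusted p = 1.11e-05), Det1, for a part of a COP1 ubiquitin ligase, by 2.52 ± 0.157 (adjusted p = 1.83e-09) and Tceanc by 2.49 ± 0.44 (adjusted p = 0.0012). The highest gene was Cacna1s, for a muscle calcium channel (9.94 against 2.07 CPM; 2.49 ± 0.441; adjusted p = 0.00122), followed by the linker histone gene Hist1h1c (23.5 against 7.44 CPM; 1.75 ± 0.418; adjusted p = 0.0225). Whether poly(A) selection of the RNA affected the counts of this histone gene was not tested. Among 23501 genes tested with edgeR, 452 fell and 24 rose, and with paired cultures as a block 954 fell and 495 rose. Each of the 476 genes was also called with the block. Hist1h1c lost its call without any 1 of 6 of the 12 libraries (adjusted p 0.0521 to 0.123, highest without Bod1L wild type 2i replicate 1).

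In single media Ccdc191 and Cbr4 were again among the lowest genes of Bod1L knockout cells, falling by 3.64 ± 0.442 and 3.62 ± 0.532 in 2i (adjusted p = 2.13e-04 and 0.00175, n = 2), and by 3.05 ± 0.426 and 2.98 ± 0.518 in FCS (adjusted p = 0.00114 and 0.0131). In EpiSC medium Ccdc191 fell by 3.33 ± 0.431 (adjusted p = 2.84e-04), Det1 by 3.17 ± 0.28 (adjusted p = 1.99e-06) and Cbr4 by 3.04 ± 0.514 (adjusted p = 0.00513). Serpine2, for a protease inhibitor, rose by 1.43 ± 0.284 in 2i (adjusted p = 0.0212). In 2i 86 genes fell and 2 rose, in FCS 45 fell and none of the genes tested rose (edgeR; 1074 genes below an unadjusted p of 0.05, DESeq2 8 higher), and in EpiSC medium 101 fell and 2 rose. Called in both media were 38 lowered genes for 2i and FCS, 55 for 2i and EpiSC medium and 28 for FCS and EpiSC medium. With the block these were 219, 236 and 183. A test for Bod1L effects that differ between media called 0 genes with edgeR, 0 with the block and 0 with DESeq2, and 244 had an unadjusted p below 0.05.

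These single-medium counts depended on the fit and on single libraries. Genes lower and higher in Bod1L knockout cells with the block were 424 and 234 in 2i, 318 and 73 in FCS and 384 and 131 in EpiSC medium. Without 1 library, the 88 genes of 2i became 8 (wild type replicate 1) or 7 (knockout replicate 2), and the 45 of FCS became 9 and 8 without knockout replicates 1 and 2, and 10 and 6 without wild type replicates 1 and 2. The 103 of EpiSC medium became 42 and 11 without knockout replicates 1 and 2, and 39 and 49 without wild type replicates 1 and 2. An arm left with 1 library was assumed to vary like the other groups. Serpine2 in 2i lost its call without any 1 of 3 of the 4 libraries (adjusted p 0.11 to 0.818, highest without wild type replicate 1). Cbr4 lost its call in 2i without wild type replicate 1 or knockout replicate 2 (adjusted p = 0.0737 and 0.11), in FCS without any 1 of 4 of the 4 libraries (adjusted p 0.0558 to 0.182) and in EpiSC medium without knockout replicate 2 (0.233). Ccdc191 in FCS lost it without knockout replicate 2 (0.0628).

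More genes were called in Setd1a than in Bod1L knockout cells. Hsf2bp, coding for a BRCA2-binding protein, fell from 31.3 to 1.78 CPM on average (-4.04 ± 0.325, n = 6; adjusted p = 1.78e-08). Cbr4 fell by 3.54 ± 0.31 (adjusted p = 4.65e-08), Ccdc191 by 3.36 ± 0.25 (adjusted p = 5.26e-09), Det1 by 3.32 ± 0.164 (adjusted p = 9.72e-12), the testis cytochrome c gene Cyct by 2.94 ± 0.634 (adjusted p = 0.004) and Ccdc91 by 2.91 ± 0.218 (adjusted p = 5.55e-09). Gatb fell by 2.85 ± 0.186 (adjusted p = 8.02e-10), Alg8 by 2.79 ± 0.305, Rfesd by 2.76 ± 0.254 and Ercc6l2, for a helicase-like protein, by 2.74 ± 0.138 (8.76 against 58.6 CPM; adjusted p = 9.72e-12). Pramel7 (3.01 ± 0.883; adjusted p = 0.0337), the cyclooxygenase gene Ptgs2 (2.99 ± 0.669; 24.8 against 3.54 CPM; adjusted p = 0.00541) and Pramel6 (2.79 ± 0.659; adjusted p = 0.0105) rose most. Reads of the Pramel family are hard to place among its many copies, so the identity of these 2 members is uncertain. In total 1308 genes fell and 773 rose (edgeR), and with paired cultures as a block 2752 fell and 3360 rose. Without 1 library the 2081 genes called became 1355 (knockout 2i replicate 1), 1370 and 1312 (wild type 2i replicates 1 and 2), 1321 (knockout FCS replicate 2) or 1355 (knockout EpiSC replicate 1). Pramel7 lost its call without any 1 of 10 of the 12 libraries (adjusted p 0.0517 to 1, highest without knockout EpiSC replicate 1, where its log2 fold change was 0.77). Ptgs2 and Pramel6 lost theirs without knockout EpiSC replicate 1 (2.02 and 1.69; adjusted p = 0.052 and 0.286).

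In each medium Hsf2bp, Cbr4 and Det1 or Ccdc191 were among the lowest genes of Setd1a knockout cells. In 2i Hsf2bp fell by 4.84 ± 0.583 (adjusted p = 4.1e-05, n = 2), the Nodal antagonist gene Lefty1 by 4.28 ± 1.05 (adjusted p = 0.0348) and Cbr4 by 3.54 ± 0.543, while the retinoic acid hydroxylase gene Cyp26a1 rose by 3.36 ± 0.547 (adjusted p = 0.00119). In FCS Hsf2bp fell by 3.64 ± 0.546 (adjusted p = 8.25e-04), Det1 by 3.38 ± 0.283 and Cbr4 by 3.26 ± 0.527, and the stress-response gene Ddit3 rose by 2.09 ± 0.409 (adjusted p = 0.00998). In EpiSC medium Oxld1 fell by 4.34 ± 0.708 (adjusted p = 0.00113), Cbr4 by 3.83 ± 0.544 and Hsf2bp by 3.65 ± 0.56, and Galnt18, for a glycosyltransferase, rose by 3.23 ± 0.79 (adjusted p = 0.0354). Counts of lower and higher genes were 338 and 59 in 2i, 174 and 5 in FCS and 328 and 33 in EpiSC medium, and with the block 1505 and 1405, 601 and 318, and 1333 and 1468. The test for Setd1a effects differing between media called 0 genes with edgeR (471 below an unadjusted p of 0.05), 42 with the block and 1 with DESeq2, and 7 with edgeR without Setd1a knockout 2i replicate 1.

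Without 1 library, the 397 Setd1a-responsive genes of 2i became 107 and 72 (knockout replicates 1 and 2) or 147 and 148 (wild type replicates 1 and 2). The 179 of FCS became 38 and 42 (knockout replicates 1 and 2) or 100 and 91 (wild type replicates 1 and 2), and the 361 of EpiSC medium became 105 (knockout replicate 1) or 126 (wild type replicate 2). Lefty1 in 2i and Ddit3 in FCS lost their calls without any 1 of 4 of the 4 libraries (adjusted p 0.107 to 0.353 and 0.0515 to 0.192). Cbr4 lost its call in 2i without knockout replicate 2 (0.0586) and in FCS without knockout replicates 1 or 2 (0.063 and 0.0742). Hsf2bp lost it in FCS without knockout replicate 2 (0.0504), Oxld1 in EpiSC medium without knockout replicate 1 (0.0581), and Galnt18 without any 1 of 3 of the 4 libraries (0.127 to 0.681, highest without knockout replicate 1, where its log2 fold change was 1.44).

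Genes lowered by Bod1L loss were nearly always lowered by Setd1a loss as well. Of 452 genes lowered in Bod1L and 1308 in Setd1a knockout cells, 415 were shared, where 25.2 would be shared at random, and 447 of the 452 lay below 0 in the Setd1a line. With the block 846 genes were shared, of 954 and 2752 (111.7 at random). The 452 genes had a median log2 fold change of -1.10 in the Bod1L line, -1.33 in the Setd1a line and -0.05 in the Mll2 line. A difference between these medians was not tested. Shared raised genes numbered 18, of 24 and 773 (0.789 at random). Shared lowered genes numbered 80 in 2i (1.24 at random), 36 in FCS (0.333) and 94 in EpiSC medium (1.41). Across the 12244 genes at 5 CPM or more, the averaged changes of the Bod1L and Setd1a lines had a Pearson r of 0.701 across genes. Bod1L and Mll2 knockout cells shared 4 lowered genes (2.87 at random) and Setd1a and Mll2 knockout cells 8 (8.29 at random). With the block these were 90 (46.1 at random) and 214 (133 at random), so the overlap passed the random level in that fit. Setd1a and Mll2 knockout cells shared 7 raised genes (0.46 at random).

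A direct test of Bod1L against Setd1a effects, averaged over media, called Bod1l itself as the 1 gene of 23501 (-2.41 ± 0.195; adjusted p = 3.78e-07). In 2i it called 0 genes with edgeR (424 below an unadjusted p of 0.05), 11 with the block and 1 with DESeq2. Bod1l was the 1 gene called in FCS (-2.94 ± 0.34; adjusted p = 3.11e-04) and in EpiSC medium (-2.30 ± 0.338; adjusted p = 0.0153). With the block 179 genes differed on average, and DESeq2 called 30. Without 1 library the averaged count became 4 (Bod1L knockout 2i replicate 2), 3 (Bod1L knockout FCS replicate 1), 2 (Bod1L wild type EpiSC replicate 2), 2 (Setd1a knockout EpiSC replicate 2) or 4 (Setd1a wild type EpiSC replicate 2). The EpiSC count became 0 without any 1 of the 8 libraries except Bod1L knockout EpiSC replicate 2.

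**Figure D2:**
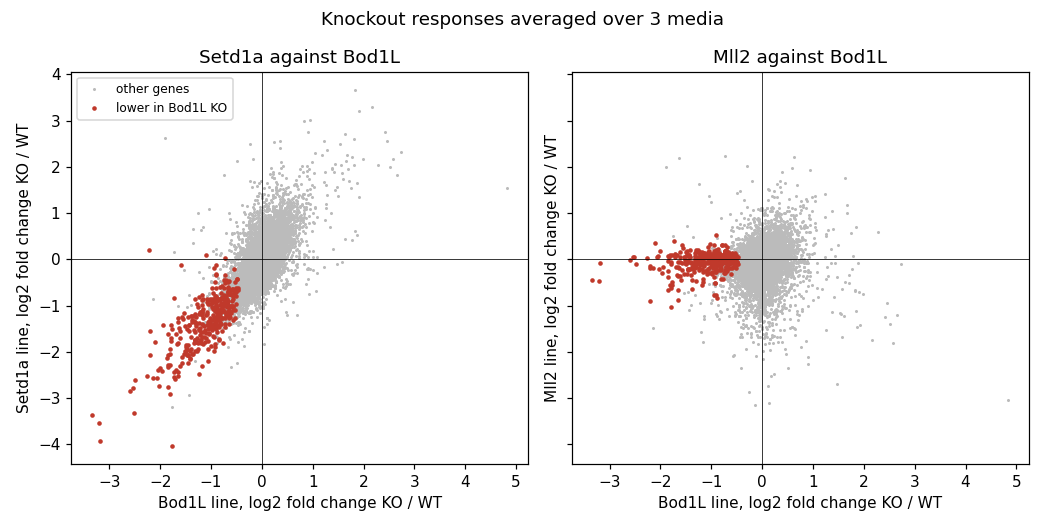
Averaged log2 fold changes, knockout against wild type, of single genes in the Setd1a or Mll2 line against the Bod1L line. Red points are genes called lower in Bod1L knockout cells, grey points are other genes, and every gene shown had a mean of at least 5 CPM.

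A part of the DNA repair genes lay lower in both Bod1L and Setd1a knockout cells. Fignl1, coding for an ATPase of homologous recombination, fell by 1.32 ± 0.134 in Bod1L (adjusted p = 1.75e-06, n = 6) and 1.35 ± 0.133 in Setd1a knockout cells (adjusted p = 2.6e-07). Babam2 of the BRCA1-A complex fell by 1.24 ± 0.145 and 1.38 ± 0.146, Palb2, which links BRCA1 to BRCA2, by 0.89 ± 0.113 and 1.42 ± 0.114, and Brca2 by 1.27 ± 0.164 in Bod1L knockout cells (adjusted p = 3e-05). Of 140 repair genes, 21 fell and none of the 140 rose with Bod1L loss on average (edgeR; 43 below an unadjusted p of 0.05; 1 higher with DESeq2; 32 fell and 2 rose adjusted over the list alone, 35 and 3 with the block). With Setd1a loss 46 fell and 1 rose (58 and 5 over the list alone, 65 and 8 with the block). Over all 23501 genes tested, 452 fell with Bod1L loss and 1308 with Setd1a loss on average. Of the 140 repair genes, 84 lay below 0 for Bod1L on average (quartiles -0.474 to 0.106) and 100 for Setd1a (-0.703 to 0.03). Median log2 fold changes of the 140 genes were -0.16 in 2i, -0.08 in FCS, -0.02 in EpiSC medium and -0.05 on average for Bod1L, and -0.37, -0.17, -0.34 and -0.30 for Setd1a. The camera test called the list lower in every case (Bod1L adjusted p = 3.91e-13, 7.62e-05, 2.69e-07 and 1.41e-11; Setd1a 9.13e-12, 6.32e-12, 2.34e-14 and 6.90e-15). With an estimated correlation each call held (adjusted p = 0.00847 for Bod1L in 2i and on average, 0.0391 in EpiSC medium, and 0.00847 in each Setd1a comparison), except Bod1L in FCS, with adjusted p = 0.107 with an estimated correlation. With the block and an estimated correlation together every call was lost (adjusted p = 0.0686 for Bod1L in 2i and on average and in each Setd1a comparison, and 0.305 and 0.108 for Bod1L in FCS and EpiSC medium).

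Within single media, 8, 5 and 9 repair genes fell with Bod1L loss in 2i, FCS and EpiSC medium (17, 15 and 18 over the list alone; 20, 17 and 21 with the block). With Setd1a loss 20, 11 and 22 fell (31, 24 and 29 over the list alone; 39, 23 and 40 with the block). The Bod1L FCS median became -0.02 without knockout replicate 1 and 0.02 without wild type replicate 2, so its size and sign depended on single libraries. In Mll2 knockout cells edgeR called 0 of the 140 repair genes in 2i, FCS, EpiSC medium and on average (12, 0, 3 and 7 below an unadjusted p of 0.05; DESeq2 called 0, 0, 0 and 1). With the block 8 fell and 1 rose in 2i, and 5 fell and 3 rose on average. Their medians were -0.11 in 2i (camera adjusted p = 0.108), 0.08 in FCS (0.00782; adjusted p = 0.278 with an estimated correlation), 0.05 in EpiSC medium (0.0804) and 0.02 on average (0.401). The Mll2 2i median was -0.11 (adjusted p = 0.0114) without wild type replicate 2, the FCS median 0.06 (0.164) without knockout replicate 1, and the EpiSC median 0.10 (0.00949) without wild type replicate 1 and 0.08 (0.00664) without knockout replicate 2.

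Homologous recombination was the 1 repair list whose fall was still called with an estimated correlation. Of 40 genes 9 fell in Bod1L and 17 in Setd1a knockout cells (13 and 20 over the list alone; 13 for Bod1L with the block), with medians of -0.13 and -0.34 (camera adjusted p = 5.82e-12 and 2.32e-13; both 0.0234 with an estimated correlation, and 0.204 with the block and an estimated correlation together). In the Fanconi anaemia pathway (24 genes) Fancd2 fell by 1.33 ± 0.149 in both lines, Fan1 by 1.23 ± 0.21 and 1.51 ± 0.213, and Fance in Setd1a knockout cells by 1.25 ± 0.179. Called there were 3 lower genes for Bod1L, and 5 lower and 1 higher for Setd1a (camera adjusted p = 0.0435 and 0.0183; adjusted p = 0.386 and 0.311 with an estimated correlation, 0.14 and 0.0703 with the block). Among damage checkpoint genes (22), Rad1 fell by 0.88 ± 0.133 and 1.05 ± 0.133, and Atr, for the kinase that senses single-stranded DNA, by 1.22 ± 0.213 and 1.49 ± 0.215. Of the excision and mismatch repair genes (40), Parp2 fell by 0.80 ± 0.124 and 1.40 ± 0.126, and Mlh3 by 1.02 ± 0.174 and 0.97 ± 0.173.

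Among the 14 end-joining genes Prkdc, for the catalytic subunit of the DNA-dependent kinase, fell by 1.23 ± 0.208 in Bod1L knockout cells (adjusted p = 7.7e-04), Xrcc4 by 0.89 ± 0.164 and Xrcc5 by 1.06 ± 0.2. In Setd1a knockout cells Xrcc5 fell by 1.42 ± 0.202 (adjusted p = 4.4e-05), Xrcc4 by 1.15 ± 0.164 and Poll by 1.51 ± 0.22. For checkpoint, excision and end-joining lists, 2, 3 and 4 genes fell with Bod1L loss (4, 7 and 4 over the list alone; 10 excision genes with the block) and 8, 10 and 6 with Setd1a loss. Camera adjusted p was 0.0085, 0.00395 and 6.25e-04 for Bod1L, and 3.66e-05, 3.38e-05 and 0.00202 for Setd1a. These calls were lost with adjusted p = 0.441, 0.288 and 0.217, and 0.215, 0.128 and 0.282 with an estimated correlation. Differences between lines were tested after the values were seen. The repair list lay 0.19 higher for Bod1L than for Setd1a (camera adjusted p = 8.19e-06), 0.12 lower for Bod1L than for Mll2 (2.98e-09) and 0.30 lower for Setd1a than for Mll2 (1.25e-14), of which the last held (adjusted p = 0.0298 with an estimated correlation, against 0.214 and 0.095).

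**Figure D3:**
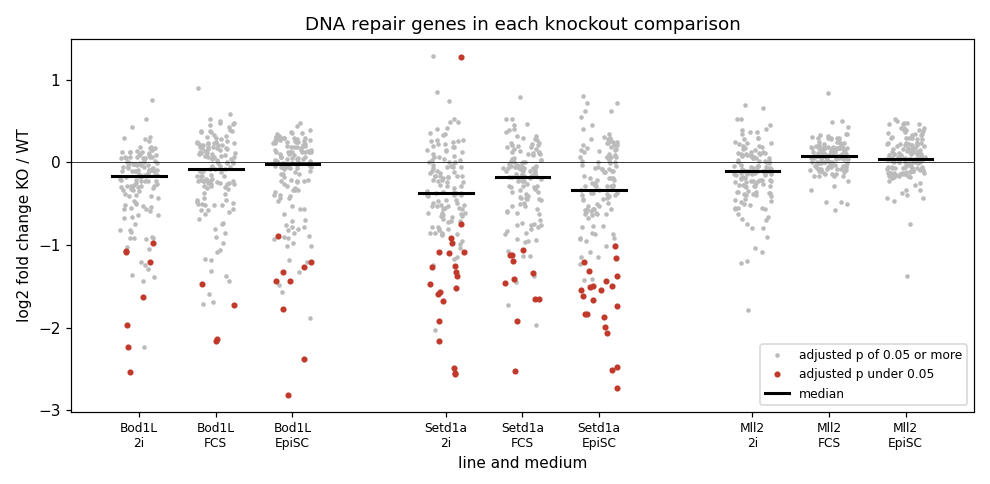
Log2 fold changes of the 140 DNA repair genes in each line and medium, knockout against wild type. Points are single genes, red where called with edgeR, and bars are medians.

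The genes that fell most in Mll2 knockout cells were others than in the Bod1L and Setd1a lines. Averaged over the media, Il3ra, coding for an interleukin receptor subunit, fell by 3.17 ± 0.467 (adjusted p = 0.00129, n = 6), the apoptosis protease gene Casp8 by 3.11 ± 0.466 (adjusted p = 0.00138), Magohb, for an exon junction protein, by 2.75 ± 0.476 (adjusted p = 0.0048) and Rimkla by 2.52 ± 0.318 (adjusted p = 3.61e-04). Inka2 rose by 1.34 ± 0.282 (adjusted p = 0.021) and Plk2, for a kinase induced by p53, by 1.13 ± 0.261 (131 against 58.9 CPM; adjusted p = 0.042). In 2i the esterase gene Ces2g rose by 4.72 ± 1.02 (adjusted p = 0.0342), Magohb fell by 5.23 ± 0.954 (adjusted p = 0.0101), the Wnt receptor gene Fzd6 by 4.06 ± 0.449 (adjusted p = 1.33e-04) and the microRNA regulator gene Lin28b by 3.97 ± 0.581 (adjusted p = 0.00211). Averaged counts were 149 lower and 14 higher, and with paired cultures as a block 1136 lower and 557 higher. In 2i 101 genes fell and 8 rose, and with the block 991 fell and 645 rose. Without wild type 2i replicate 2 the averaged log2 fold change of Il3ra was -2.18. In FCS and EpiSC medium edgeR called 0 genes (615 and 952 below an unadjusted p of 0.05), the block 194 and 508, and DESeq2 5 and 44.

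Gtpbp10, coding for a mitochondrial ribosome assembly factor, was the 1 gene whose Mll2 effect differed between media. Its log2 fold change was -2.62 in 2i, and 2.49 and 2.89 higher in FCS and EpiSC medium (adjusted p = 0.0416); 378 genes were called with the block and 24 with DESeq2. That count became 114 without Mll2 wild type 2i replicate 1, 1 without wild type FCS replicate 1, and became 0 without any 1 of the other 10 libraries. The library labelled Mll2 wild type in 2i, replicate 2, entered these counts: the 109 genes of 2i became 37 without it, 1585 without its partner, replicate 1, and 18 and 26 without knockout replicates 1 and 2. The averaged 163 became 102 (knockout 2i replicate 1), 310 and 98 (wild type 2i replicates 1 and 2), 101 (wild type FCS replicate 1), 100 (knockout FCS replicate 2), 106 (wild type EpiSC replicate 1) or 82 (knockout EpiSC replicate 2), and the EpiSC count 3 without wild type EpiSC replicate 2. Inka2 and Plk2 lost their calls without any 1 of 7 and of 9 of the 12 libraries (adjusted p 0.0723 to 0.106 and 0.0532 to 0.234). Ces2g and Magohb in 2i lost theirs without any 1 of 3 of the 4 libraries (adjusted p 0.0763 to 0.411 and 0.082 to 0.25, both highest without wild type replicate 2), and Lin28b without knockout replicate 2 (0.0598).

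Direct tests set the Mll2 response apart from the other 2 lines. Det1 lay lower by 2.57 ± 0.213 for Bod1L than for Mll2 (adjusted p = 5.65e-07), Bod1l by 2.06 ± 0.194 and Gatb by 2.58 ± 0.247 (each adjusted p = 2.53e-06). Pls1, for an actin-bundling protein, was higher by 2.67 ± 0.33 (adjusted p = 7.34e-05) and Chst10 by 2.15 ± 0.296 (adjusted p = 3.25e-04). Against Mll2, Setd1a effects were lower for Det1 (-3.37 ± 0.217; adjusted p = 3.51e-09), Ercc6l2 (-2.53 ± 0.185; adjusted p = 2.46e-08), Thap6 (-2.56 ± 0.209) and Supv3l1, for a mitochondrial RNA helicase (-1.83 ± 0.151; both adjusted p = 1.34e-07). They were higher for Fzd6 (2.74 ± 0.318; adjusted p = 1.04e-05) and Adam22 (2.37 ± 0.304; adjusted p = 3.36e-05). Between Bod1L and Mll2 179 genes lay lower and 62 higher, and between Setd1a and Mll2 469 and 205. With the block 1308 and 3305 genes differed, and with DESeq2 501 and 1200.

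The 29 p53 target genes had medians above 0 in knockout cells of each line. In Setd1a knockout cells Btg2, coding for an antiproliferative factor, rose by 1.03 ± 0.181 (adjusted p = 5.45e-04, n = 6), Mdm2, the gene of the p53 ubiquitin ligase, by 1.24 ± 0.246 (adjusted p = 0.0018), Plk2 by 1.31 ± 0.262 and Ccng1 by 0.79 ± 0.158. Btg2 rose by 0.70 ± 0.18 in Bod1L knockout cells (adjusted p = 0.0401), losing its call without any 1 of 9 of the 12 libraries (adjusted p 0.0597 to 0.219, highest without knockout EpiSC replicate 2). Called higher were 1 gene for Bod1L, 11 for Setd1a and 1 for Mll2 (3 and 18 over the list alone for Bod1L and Setd1a; 10, 20 and 7 with the block). Medians were 0.35, 0.58 and 0.29 (camera adjusted p = 2.93e-08, 3.72e-08 and 5.71e-05; adjusted p = 0.215, 0.215 and 0.346 with an estimated correlation). Each of the 6 culture pairs of each line had a higher mean over the list in the knockout culture (means 0.388, 0.624 and 0.256; exact sign-change p = 0.0312 each, the smallest possible). The Mll2 mean came largely from 2i (0.510 and 0.491), with 0.0038 and 0.344 in FCS and 0.0121 and 0.177 in EpiSC medium, while the Setd1a pairs had 0.409 and 0.499 in 2i, 0.780 and 0.648 in FCS and 0.837 and 0.572 in EpiSC medium. With media pooled, exact permutation p for differences between lines was 0.0151 for Bod1L against Setd1a, 0.219 for Bod1L against Mll2 and 0.013 for Setd1a against Mll2.

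Some replication and cholesterol genes fell with Setd1a loss. Mcm10, coding for a replication initiation factor, fell by 0.51 ± 0.107 (adjusted p = 0.0031) and Rfc4, for a clamp loader subunit, by 0.66 ± 0.156 (adjusted p = 0.0087). Of 40 replication and S phase genes, 11 fell (15 over the list alone, 25 with the block) with a median of -0.39 (camera adjusted p = 6.58e-11, and 0.33 with an estimated correlation). In Bod1L knockout cells the median was -0.03 and edgeR called 0 of the 40 (1 below an unadjusted p of 0.05; 0 with DESeq2; camera adjusted p = 0.386). Of 27 G2 and mitosis genes the cyclin gene Ccnb2 was the 1 called, falling by 1.10 ± 0.171 (adjusted p = 1.3e-04). The cholesterol synthesis genes Fdps and Fdft1 fell by 0.92 ± 0.176 and 0.74 ± 0.147 (adjusted p = 0.0013 and 0.0018), with 6 of 23 genes lower (9 over the list alone, 14 with the block; median -0.37; camera adjusted p = 1.21e-05, and 0.431 with an estimated correlation). In Mll2 knockout cells the cholesterol median was -0.29 with 0 genes called by edgeR (6 below an unadjusted p of 0.05; 0 with DESeq2; 5 lower over the list alone, 9 lower with the block; camera adjusted p = 1.37e-06, and 0.355 with an estimated correlation). The stress-response genes Ddit3 and Slc7a11 rose by 1.37 ± 0.232 and 1.59 ± 0.345 with Setd1a loss (adjusted p = 3.4e-04 and 0.0042), 2 of 17 integrated stress response genes (5 with the block; median 0.14; camera adjusted p = 0.0862).

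Single ERK and Wnt response genes rose with Setd1a loss. Spry2, coding for an inhibitor of ERK signalling, rose by 0.62 ± 0.143 (adjusted p = 0.0072) and Phlda1 by 1.15 ± 0.308 (adjusted p = 0.02) in Setd1a knockout cells, 2 of 15 ERK response genes (6 over the list alone, 8 higher and 1 lower with the block; median 0.61; camera adjusted p = 0.0102, and 0.579 with an estimated correlation). Phlda1 lost its call without any 1 of 6 of the 12 libraries (adjusted p 0.0514 to 0.071). In the Mll2 line the ERK median was 0.46 with 0 genes called by edgeR (6 below an unadjusted p of 0.05; 0 with DESeq2; 4 over the list alone, 9 with the block; camera adjusted p = 1.34e-04, and 0.311 with an estimated correlation). Ccnd2, for a D-type cyclin, was the 1 of 11 Wnt response genes called with Setd1a loss (1.62 ± 0.395; adjusted p = 0.011; 0.0745 without knockout EpiSC replicate 1). In Bod1L knockout cells edgeR and DESeq2 both called 0 of the ERK, Wnt, cholesterol and stress-response genes (1, 0, 0 and 1 below an unadjusted p of 0.05), with medians of 0.13, 0.03, 0.08 and -0.15.

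Few pluripotency genes were called in the knockouts. Lin28a, coding for a microRNA-binding protein, was the 1 of 11 general pluripotency genes called with Setd1a loss (-1.35 ± 0.297; adjusted p = 0.0047; 1 higher and 4 lower with the block), and Dppa3, a naive-state and germline gene, the 1 of 18 naive genes (-1.54 ± 0.484; adjusted p = 0.0499; 5 higher and 2 lower with the block). The formative genes Zic5 and Zic2 fell by 0.92 ± 0.246 and 1.16 ± 0.319 (adjusted p = 0.02 and 0.024), 2 of 18 (2 higher and 7 lower with the block). Medians for Setd1a were -0.08, 0.24 and -0.34 for the general, naive and formative lists (camera adjusted p = 0.2, 0.606 and 0.158). With the block the formative list had a camera adjusted p of 0.048, a call lost with the block and an estimated correlation together. The medians were 0.07, -0.04 and -0.02 for Bod1L (0.968, 0.951 and 0.66) and 0.03, -0.10 and 0.16 for Mll2 (0.458, 0.695 and 0.786). In Bod1L knockout cells edgeR and DESeq2 called 0 genes of the 3 lists (0, 0 and 1 below an unadjusted p of 0.05), and the block 1 lower, 2 higher and 1 higher. In Mll2 knockout cells edgeR called 0 (1, 1 and 0 below an unadjusted p of 0.05), DESeq2 0, 1 lower and 0, and the block 2 higher, 2 lower, and 2 higher and 1 lower. Dppa3, Zic5 and Zic2 lost their calls without any 1 of 10, 5 and 7 of the 12 libraries (adjusted p 0.052 to 0.15, 0.0539 to 0.0985 and 0.0532 to 0.14).

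Lineage genes moved singly with Setd1a loss. The basement membrane genes Col4a1 and Lama1 rose by 1.77 ± 0.426 (adjusted p = 0.0098) and 1.25 ± 0.337 (adjusted p = 0.02), part of 3 of 16 primitive endoderm genes (7 with the block; median 0.65; camera adjusted p = 0.00753, and 0.456 with an estimated correlation). Lefty1 fell by 2.32 ± 0.547 (adjusted p = 0.0082), the 1 of 17 mesendoderm genes called, and Fbln2 rose by 1.26 ± 0.376 (adjusted p = 0.037), the 1 of 17 feeder genes (8 with the block). The 16 neural genes had a median of -0.08 (camera adjusted p = 0.77). Hoxc13 was the 1 of 38 Hox genes called (1.07 ± 0.332; adjusted p = 0.044; 5 with the block), and edgeR called 0 of 11 trophoblast genes (1 below an unadjusted p of 0.05; 0 with DESeq2; 4 higher with the block; median 0.55). In Mll2 knockout cells the endoderm gene Sox7 rose by 1.72 ± 0.383 (adjusted p = 0.032), and Hox genes had a median of 1.62 in EpiSC medium with 0 called by edgeR (7 below an unadjusted p of 0.05; 0 with DESeq2; 5 with the block; camera adjusted p = 6.99e-11, and 0.355 with an estimated correlation). Col4a1 lost its call without knockout FCS replicate 2 or EpiSC replicate 1 (adjusted p = 0.0871 and 0.08), with a log2 fold change of 1.16 without the first. Lama1, Fbln2, Hoxc13 and Sox7 lost theirs without any 1 of 5, 11, 10 and 11 of the 12 libraries (adjusted p up to 0.148, 0.184, 0.122 and 0.11).

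The 2-cell-like genes, transcripts of a rare state resembling the early embryo, had large medians and few calls. Zscan4a and Zscan4c rose by 2.57 ± 0.792 and 2.75 ± 0.863 in Setd1a knockout cells (adjusted p = 0.0441 and 0.0482), although reads of this multi-copy family are hard to place and the members are uncertain. They lost their calls without any 1 of 10 and of 9 of the 12 libraries (adjusted p 0.0541 to 0.286 and 0.0565 to 0.284), and their log2 fold changes were 1.51 and 1.69 without knockout EpiSC replicate 1. Of 13 such genes 2 rose with Setd1a loss (9 over the list alone, 12 with the block; median 2.34; camera adjusted p = 4.24e-05, and 0.623 with an estimated correlation). With Bod1L loss the median was 2.16 with 0 called by edgeR (2 below an unadjusted p of 0.05; 1 with DESeq2; 2 with the block; camera adjusted p = 0.0156, and 0.805 with an estimated correlation). In the Mll2 line it was -4.09 in 2i, with 0 called by edgeR (11 below an unadjusted p of 0.05; 1 with DESeq2; 9 lower over the list alone, 12 lower with the block; camera adjusted p = 2.35e-08, and 0.393 with an estimated correlation). The 2 Mll2 wild-type libraries in 2i themselves lay apart in this list, with a median log2 difference of -2.447 for replicate 2 against replicate 1. Dmrt1, a testis transcription factor gene, fell by 1.99 ± 0.366 in Mll2 knockout cells (adjusted p = 0.00684), the 1 of 22 germline genes called (5 with the block). In the COMPASS list (21 genes), Bod1l was the 1 gene edgeR called in any averaged comparison, in the Bod1L line. For the Setd1a average 6 of the 21 were below an unadjusted p of 0.05 (0 with DESeq2). With the block Setd1a was called in its own line (-0.377; adjusted p = 0.0285).

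Several mitochondrially encoded transcripts rose in Setd1a knockout cells in 2i and EpiSC medium. Averaged over the media, mt-Nd1 rose by 1.29 ± 0.176 (adjusted p = 2.5e-05, n = 6), mt-Nd3 by 1.42 ± 0.196, mt-Nd2 by 1.34 ± 0.192 and mt-Atp8 by 1.12 ± 0.214, among 8 of 13 genes called (median 0.81; camera adjusted p = 3.44e-08, and 0.29 with an estimated correlation). Called higher were 5 genes in 2i (9 with the block) and 4 in EpiSC medium (10 with the block), with medians of 1.10 and 1.18, and in FCS edgeR called 0 (3 below an unadjusted p of 0.05, 0 with DESeq2 and 0 with the block), with a median of 0.15 (camera adjusted p = 0.968). In Bod1L knockout cells mt-Nd3 rose by 0.82 ± 0.193 (adjusted p = 0.0198) and mt-Nd2 by 0.72 ± 0.19 (adjusted p = 0.0492), with a median of 0.33 (camera adjusted p = 3.53e-05, and 0.435 with an estimated correlation). These 2 lost their calls without any 1 of 5 and of 10 of the 12 libraries (adjusted p 0.0533 to 0.0866 and 0.0847 to 0.281). Mitochondrial genes made up 7.32% and 7.71% of reads in Setd1a knockout 2i libraries against 4.11% and 3.43% in wild type, 6.27% and 3.89% against 3.42% and 1.98% in EpiSC medium, and 4.33% and 4.25% against 5.09% and 3.60% in FCS. The 7.71% library, Setd1a knockout 2i replicate 2, also stood apart with 5.04% of counts in ribosomal repeat genes, and the 7.32% library was of the later run while the wild-type 2i libraries were of the earlier 1. In the Bod1L line these were 5.60% and 5.48% against 4.31% and 4.22% in 2i, 3.89% and 2.46% against 3.89% and 3.62% in FCS, and 3.94% and 4.71% against 2.41% and 2.50% in EpiSC medium. Hist1h1c was the 1 of 21 replication-dependent histone genes called in each of the Bod1L and Setd1a lines, rising by 1.54 ± 0.42 with Setd1a loss (adjusted p = 0.022; lost without any 1 of 6 of the 12 libraries, adjusted p 0.0589 to 0.278; log2 fold change 0.74 without knockout EpiSC replicate 1). Histone medians were 0.68 for Bod1L (camera adjusted p = 6.65e-05, and 0.641 with an estimated correlation) and 0.25 for Setd1a (0.526). The RNA was poly(A)-selected, and an effect of that step on the histone counts was not tested.

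Genes lowered in Bod1L or Setd1a knockout cells were often 1 of 2 genes transcribed head to head. Of the 367 protein-coding genes among the 415 lowered in both lines, 91 (24.8%) had a neighbour starting within 1000 bp on the opposite strand, against a median of 10.1% in 10000 random lists of matched expression (highest 16.1%; permutation p = 1e-04, the smallest possible). The share was 24.5% of 396 genes lowered with Bod1L loss and 20.1% of 1100 lowered with Setd1a loss (random medians 9.8% and 10.3%, permutation p = 1e-04 each). It was 17.7% of the 733 called lower with Setd1a and not with Bod1L loss (random median 10.4%, permutation p = 1e-04). For the 29 called lower with Bod1L and not with Setd1a loss it was 20.7% (random median 6.9%, permutation p = 0.031). For the 144 protein-coding genes lowered in Mll2 knockout cells the share was 0.7%, against a median of 8.3% in random lists (lower-tail permutation p = 1e-04). The neighbours were compared in 104 tested pairs, which also include lowered genes that are not protein-coding. Across these pairs the lowered genes had medians of -1.18 in the Bod1L and -1.42 in the Setd1a line and their neighbours 0.07 and -0.01. The lowered gene was the less abundant of the pair in 81 of 104, at 19.1 against 58.7 CPM. Of the neighbours 3 were called lower in Bod1L and 12 in Setd1a knockout cells, 2 of them in both lines, and 2 were higher with Setd1a loss. Examples picked after the values were seen were Fancd2 with Emc3 (-1.33 and 0.31 in Bod1L knockout cells) and Mcm8 with Trmt6 (-1.65 and 0.19).

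**Figure D4:**
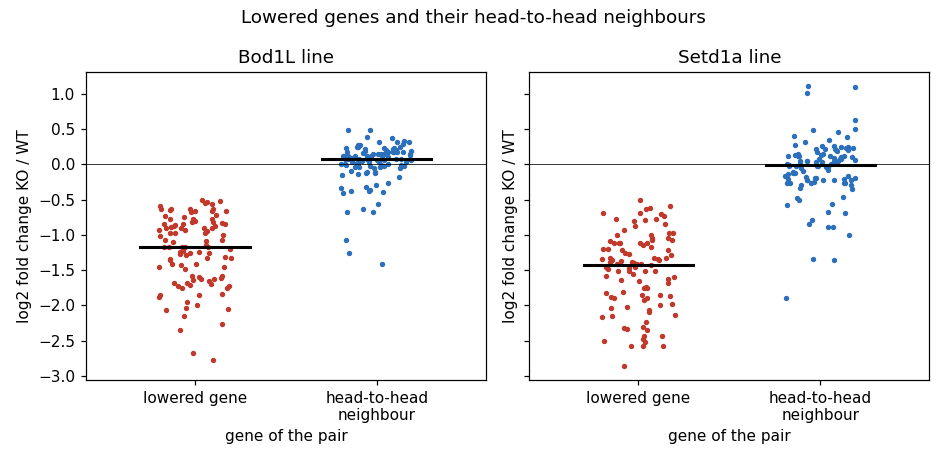
Averaged log2 fold changes of genes lowered in both Bod1L and Setd1a knockout cells and of their head-to-head neighbours. Each point is 1 gene and bars are medians.

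Wild-type cells separated strongly by medium. Between 2i and FCS (n = 6 per medium), Htr5a, for a serotonin receptor, was higher by 8.71 ± 0.778 (adjusted p = 3.5e-07), the caudal homeobox gene Cdx1 by 8.41 ± 0.366 (adjusted p = 8.58e-13) and Hoxa5 by 7.86 ± 1.01 in 2i. Lower in 2i were Enpp2 (-7.99 ± 1.1; adjusted p = 1.24e-05), the smooth muscle gene Tagln (-7.65 ± 0.896) and Car4 (-7.57 ± 0.741). Between EpiSC medium and FCS, Dnm3os (9.76 ± 1.55) and Islr (8.50 ± 1.24) were higher, and Mageb4 (-8.10 ± 1.55) and Rhox9 (-8.02 ± 0.922) lower in EpiSC medium. Between EpiSC medium and 2i, the collagen gene Col3a1 was higher by 12.1 ± 1.23 (adjusted p = 8.82e-08) and Tnc by 11.6 ± 1.27, and Bhmt lower by 10.5 ± 0.726 and Cdx1 by 10.2 ± 0.421. Genes called numbered 6533 (3398 higher and 3135 lower in 2i), 9642 and 12342 for these 3 comparisons with edgeR. All EpiSC libraries carry library numbers of the later run, and their titles name EpiSC rather than ESC. EpiSC medium, cell type and run were therefore confounded.

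Markers of each state followed the media. The naive genes Esrrb and Klf2, coding for transcription factors, were lower by 6.23 ± 0.256 and 4.95 ± 0.266 in EpiSC medium than in 2i (Esrrb adjusted p = 1.2e-13). Of 18 naive genes 18 were lower in EpiSC medium than in 2i and 17 than in FCS (camera adjusted p = 1.12e-13 and 2.26e-15; both 0.0129 with an estimated correlation). Fgf5, a formative-state growth factor gene, was higher in EpiSC medium than in 2i by 8.46 ± 0.728 (adjusted p = 4.3e-09) and Pou3f1 by 4.28 ± 0.58, with 13 of 18 formative genes higher (camera adjusted p = 3.91e-05, and 0.209 with an estimated correlation). The ERK response genes Spry4 and Egr1 lay lower in 2i than in FCS by 6.71 ± 0.369 and 6.27 ± 0.388, with 12 of 15 lower (camera adjusted p = 3.03e-09, and 0.085 with an estimated correlation). Of 38 Hox genes 33 were higher in 2i than in FCS (camera adjusted p = 2.72e-16, and 0.209 with an estimated correlation), among them Hoxa3 by 6.56 ± 0.647. The 2-cell-like genes were higher in 2i than in FCS in 13 of 13 (camera adjusted p = 9.59e-09, and 0.269 with an estimated correlation). Feeder genes were higher in EpiSC medium than in 2i in 16 of 17 (median 6.48; camera adjusted p = 6.02e-07, and 0.233 with an estimated correlation).

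The 3 wild-type lines differed from each other in 3445 genes (1656 with the block). Hprt, coding for a purine salvage enzyme, led with log2 levels 7.21 and 7.63 higher in the Setd1a and Mll2 lines than in the Bod1L line (adjusted p = 7.93e-13), and Rps3a3 lay 3.78 and 3.35 lower (adjusted p = 1.29e-12). Genes of whole chromosomes lay apart: the 1752 genes of chromosome 11 had a median log2 difference of 0.40 in the Setd1a against the Bod1L line (random lists -0.01 to 0.04), chromosome 6 genes -0.20, and 16 chromosome Y genes -1.80. In the Mll2 against the Bod1L line chromosome Y genes had a median of -5.54, chromosome 6 genes -0.21 and chromosome 1 genes 0.13. In total 10 and 9 of 21 chromosomes lay apart from random lists (adjusted p = 0.0024, the smallest possible, for those named). In knockout against wild-type cells of the same line, averaged over media, 1, 4 and 4 chromosomes did so for Bod1L, Setd1a and Mll2, among them chromosome 1 for Setd1a (median 0.15).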

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

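The tests of these values were fixed before the data were examined, except the line differences of the repair list, which were chosen after its medians were seen. Of 60 checks of a measure within 6 libraries of the same genotype and medium, 5 set 1 library apart, where chance flags about 1 in 20 groups. Bod1l stood at 263.2 CPM in the library labelled Mll2 wild type in 2i, replicate 2, above the other 5 wild-type libraries in 2i. Setd1a knockout 2i replicate 2 stood apart from the other knockout libraries in 2i in 3 related measures, with 5.042% of counts in ribosomal repeat genes, 2.655% in its largest gene, Gm42418, and 0.388% in antisense genes. Setd1a knockout EpiSC replicate 1 had 18874 genes with at least 10 counts, apart from the other knockout libraries in EpiSC medium.

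Tests of a difference between groups set apart Gtpbp10, the 1 gene whose Mll2 effect differed between media, and Bod1l, the 1 gene that differed between the Bod1L and Setd1a effects on average, the 1 in FCS and the 1 in EpiSC medium. Against the Mll2 effect, 241 genes differed for Bod1L, led by Det1, and 674 for Setd1a. The DNA repair list had a median difference of 0.188 for Bod1L minus Setd1a, -0.124 for Bod1L minus Mll2 and -0.304 for Setd1a minus Mll2.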

How the results depend on the processing

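Each group had 2 libraries, and averaged comparisons had 6 per arm. Knockout cells were treated with tamoxifen and wild-type cells were not, so genotype and treatment were confounded in every knockout comparison, and EpiSC medium was confounded with the later run of library numbers. Setd1a and Kmt2b totals check the deletions little. Calls are from 1 model over all 36 libraries. The settings compared moved many counts of called genes and few directions, and for every changed result below the cause was not tested. Settings written down after the data were seen were the ones leaving out a library picked for its values, the blocked list and similarity settings, and the block with an estimated correlation. RLE size factors moved none of the 25 counts.

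With DESeq2 the counts of genes changed were 198 (2i), 174 (FCS) and 254 (EpiSC) for Bod1L, 844, 359 and 760 for Setd1a, and 321, 5 and 44 for Mll2, with 389 for the Mll2 average. Genes whose effect differed were 30 for Bod1L minus Setd1a on average, 1 in 2i and 2 in EpiSC medium, 501 for Bod1L minus Mll2, 1200 for Setd1a minus Mll2, 24 for Mll2 between media and 1 for Setd1a between media. The DNA repair medians moved to -0.109 (Bod1L 2i), -0.278 (Setd1a 2i) and -0.26 (Setd1a average).

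With the paired replicates as a block the counts were 658 (2i), 391 (FCS), 515 (EpiSC) and 1449 (average) for Bod1L, 2910, 919, 2801 and 6112 for Setd1a, and 1636, 194, 508 and 1693 for Mll2. Differences were 179 for Bod1L minus Setd1a on average and 11 in 2i, 1308 for Bod1L minus Mll2, 3305 for Setd1a minus Mll2, 42 and 378 between media for Setd1a and Mll2, and 1656 among the wild-type lines. Setd1a in its own line was -0.377 on average (adjusted p = 0.0285). The block changed no other call among the targeted genes, the named genes and the repair list, and some of the list counts it moved stand beside the lists.

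Without a filter on low counts, where 39460 genes were tested, the counts were 149 and 81 for Bod1L in 2i and FCS, 775 and 706 for Setd1a in 2i and EpiSC medium, and 702, 75, 125 and 687 for Mll2 in 2i, FCS, EpiSC medium and on average. Differences were 12, 119 and 203 between media for Bod1L, Setd1a and Mll2, 63, 23, 16 and 9 for Bod1L minus Setd1a on average, in 2i, FCS and EpiSC medium, 367 for Bod1L minus Mll2 and 1041 for Setd1a minus Mll2. With a stricter filter (18149 genes) the Mll2 EpiSC count was 6 and the averaged Bod1L minus Setd1a count 3.

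With only the groups compared in the fit, the counts were 0 in 2i, 0 in FCS, 0 in EpiSC medium and 240 on average for Bod1L, 7029, 0 and 0 in 2i, FCS and EpiSC medium for Setd1a, and 0 in 2i and 1 on average for Mll2. Differences were 149 for Bod1L minus Mll2, 1 in 2i, 0 in FCS and 0 in EpiSC medium for Bod1L minus Setd1a, and 0 for Mll2 between media. Bod1l in its own line lost its call in each single medium (-1.738, -2.944 and -1.985 in 2i, FCS and EpiSC; adjusted p = 0.783, 0.837 and 1). Setd1a in its own line was -0.371 on average (adjusted p = 0.0329) and -0.317 in 2i (0.0374). The Mll2 EpiSC repair median of 0.042 had an adjusted p of 0.0354.

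The settings that leave out a library picked for its values filter genes and estimate dispersion afresh, while leaving out each library in turn keeps the filter and dispersion trend of the full fit, so their values differ slightly. Leaving out the Mll2 2i wild-type library that stands apart gave 68 genes for Bod1L in FCS, 32, 3 and 99 for Mll2 in 2i, EpiSC medium and on average, and 0 for Mll2 between media. Kmt2b in 2i was -0.358, and the Mll2 2i repair median -0.094 (adjusted p = 0.0142). Leaving out the Setd1a 2i knockout library with the most ribosomal repeat reads gave 73 genes for Setd1a in 2i, 1378 on average, and 0 for Mll2 between media.

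Of 312 list tests camera called 111, or 117 with the block, 6 with an estimated correlation, 28 with fry, and 0 with the block and an estimated correlation together. The 6 were homologous recombination in Bod1L knockout cells in 2i and on average and in the 4 Setd1a comparisons. With an estimated correlation the repair list in Bod1L FCS (-0.078) and Mll2 FCS (0.078) had adjusted p of 0.107 and 0.278, and with fry Mll2 FCS (0.078) had 0.449. With the block and an estimated correlation together none of the repair list calls was left, at medians of -0.16, -0.096, -0.018 and -0.073 for Bod1L in 2i, FCS, EpiSC medium and on average (adjusted p = 0.0686, 0.305, 0.108 and 0.0686), -0.365, -0.165, -0.315 and -0.282 for Setd1a (each 0.0686) and 0.078 for Mll2 in FCS (0.403). Of 78 list tests between wild-type media 42 passed, and 2 did with an estimated correlation.

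Leaving out each library in turn moved 61 counts and left 197 within a factor of 1.5, with the libraries named beside each count in the report. Genes changed ran from 7 to 80 in 2i, 6 to 10 in FCS and 11 to 49 in EpiSC medium for Bod1L, from 72 to 148, 38 to 100 and 105 to 419 for Setd1a (1312 to 2584 on average), and from 18 to 1585 in 2i, 0 to 3 in EpiSC medium and 82 to 310 on average for Mll2. Differences ran from 0 to 7 and 0 to 114 between media for Setd1a and Mll2, and from 1 to 4 on average and 0 to 1 in EpiSC medium for Bod1L minus Setd1a. Repair medians ran from -0.216 to 0.023 for Bod1L in FCS, -0.113 to -0.084 for Mll2 in 2i, 0.055 to 0.116 in FCS and 0.041 to 0.096 in EpiSC medium, and Kmt2b in 2i from -0.376 to 0.649. Of 171 results of named genes none changed direction in any setting, 171 of 171 kept their calls with DESeq2, with the block and with the stricter filter, and 50 lost them with only the groups compared. The named genes were picked for their calls in the main fit, so how many kept them does not measure how far calls hold in general. Bod1l in 2i was -1.774 (adjusted p = 0.0512) without Bod1L knockout 2i replicate 2.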

Other observations

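The mitochondrial translation list and its tests were chosen after lowered synthetase genes were seen among the top genes. The list was corrected once to its written form after a first output. The tamoxifen test of the genes lowered in both lines and the tests of a library label, given below, were also chosen afterwards. The other tests of this part were written down before their results were seen. Single mitochondrial translation genes were lower with Bod1L and Setd1a loss, and the list as a whole was not called with an estimated correlation. Ears2, which codes for a mitochondrial aminoacyl-tRNA synthetase, had averaged log2 fold changes of -1.85 in Bod1L and -2.29 in Setd1a knockout cells. Mrpl11, for a mitochondrial ribosomal protein, had -1.24 and -2.47. Of 94 such genes 10 were lower in Bod1L and 37 in Setd1a knockout cells with edgeR (19 and 47 with the block; list medians -0.036 and -0.385), and 7 and 9 of these were among the 17 synthetase genes, the kind that had led to the list. The 77 other genes had medians of -0.022, -0.345 and -0.101 for Bod1L, Setd1a and Mll2, with camera adjusted p = 0.00125, 1.53e-15 and 0.0238, and adjusted p = 0.696, 0.271 and 0.696 with an estimated correlation (all 94: 0.433, 0.216 and 0.696). In Mll2 knockout cells edgeR called 0 of the 94 (2 lower below an unadjusted p of 0.05; 0 with DESeq2; 0 with the block).

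The tamoxifen test of this pattern was chosen after the result was seen and the others before, but the bias test was first run in another form and corrected to its written form after that output was seen. A shared role of BOD1L and SETD1A at the 415 genes lowered in both lines stays open and was not tested, since binding and histone mark data were not analysed here. Tamoxifen treatment alone, if it acts alike in all lines, is unlikely. The same genes had a median log2 fold change of -0.05 in the treated Mll2 line (quartiles -0.188 to 0.07). Bias from GC content or gene length is unlikely too for the 333 of these genes with known GC content and at least 5 CPM. Among them 103.7% (Bod1L) and 97.7% (Setd1a) of the median change was left after removing those trends. A head-to-head promoter was present at 24.8% of the shared genes and 0.7% of those lowered with Mll2 loss. It was present at 17.7% of genes called lower with Setd1a and not with Bod1L loss (random median 10.4%, permutation p = 1e-04). Such genes may have fallen short of a call in the Bod1L line, so whether this feature was particular to the shared genes cannot be told. Its cause was not tested.

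Tests of the p53 pattern were written down before their results were seen. The p53 targets were higher in all 3 treated lines, so tamoxifen or Cre activity could have contributed to a common rise, which was 0.388 ± 0.104, 0.624 ± 0.164 and 0.256 ± 0.227 (mean ± SD over 6 pairs). With media pooled the rise differed between Setd1a and Mll2 (exact permutation p = 0.01299). A treatment effect of equal size in all lines is therefore unlikely to give the whole pattern. A treatment effect that differs between lines cannot be told apart from loss of the gene. In 2i the Mll2 pairs rose by 0.510 and 0.491 and the Setd1a pairs by 0.409 and 0.499, so there treatment could give the whole rise. Loss of repair transcripts might have added to it, as the rise went with the change of repair genes over 18 pairs (Pearson r = -0.744, permutation p = 0.00045; Spearman rho = -0.643, permutation p = 0.005; r = -0.605 without the 2 farthest pairs). Within lines r was 0.117, -0.289 and -0.858 for Bod1L, Setd1a and Mll2, and within runs -0.625 (11 pairs) and -0.936 (6 pairs), so differences between lines could carry much of it.

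The 3 tests of the label were chosen after the result was seen, and the others before, but the cell-type test was first run without the germline list and corrected to its written form after that output was seen. The library labelled Mll2 wild type in 2i, replicate 2, differed from its partner with a chi-square per degree of freedom of 324.92, the highest of the 18 groups, and held less Kmt2b than the Mll2 knockout libraries in 2i. Its difference followed gene length with a rank correlation of -0.465, beyond the highest other group (0.404), so a length-linked effect of RNA or library preparation may be part of it, while GC content is an unlikely cause (0.133, where other groups reached 0.488). Germline genes lay 1.152 higher than in the partner as the highest of 6 cell-type lists and 2-cell-like genes were at -2.447, but other replicates differed by up to -2.225 and -5.844 in these lists, so this did not set the library apart and a shift in cell state stays open. Whether it was a knockout library under this label stays open. In it, 92 genes lowered in Mll2 knockout cells in a fit without it lay 2.107 above the knockout libraries in 2i (2.192 in the partner). These genes were picked partly for being low in those same knockout libraries, and no knockout library was left out in the same way, so this test cannot decide. A stricter test from FCS and EpiSC medium had 0 genes to use with edgeR (717 lower below an unadjusted p of 0.05, and 96 with DESeq2). A library of another line is unlikely, since 18 genes particular to wild-type Mll2 cells in FCS and EpiSC medium lay 1.763 from the other lines in 2i (2.152 in the partner).

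Regrouping the libraries at random, in fits of the libraries compared alone, gave counts as large as the real split in 2 of 100 splits for the Bod1L average (358 genes; highest other 666), 1 for Setd1a (2562; 112) and 6 for Mll2 (1; 36), counting the real split itself. These fits kept the dispersion trend of the full fit and held 1 knockout term beside the media, or beside the culture pairs for differences between lines, so their counts differ from those of the other fits. For Setd1a no other split came near the real count, while for Bod1L another split passed it. Chance was therefore not excluded for Bod1L or Mll2 in this fit. The split that called 666 genes put both libraries of 2i replicate 1, FCS replicate 2 and EpiSC replicate 1 against the rest, so differences shared by both libraries of a culture pair called more genes than the knockout. With the replicate block, in 32 splits, 1 was as large for each line: Bod1L 1378 (highest other 47), Setd1a 5022 (546) and Mll2 173 (3). Between wild-type media 1 of 100 splits was as large each time, for 2i minus FCS (5643; 21), EpiSC minus FCS (8052; 1072) and EpiSC minus 2i (10134; 140), and 1 for the wild-type lines (1548; 17). For differences between lines it was 1 each for Bod1L minus Setd1a (363; 2), Bod1L minus Mll2 (1038; 1031) and Setd1a minus Mll2 (2380; 902), and the Bod1L minus Mll2 margin was narrow.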
